A study of Homo sapiens with 4 samples.

How the data were processed

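The series measured messenger RNA in WM35, a human melanoma cell line of the radial growth phase. Per the labels, cultures received either C646 at 20 µM or the solvent DMSO at 0.2%, and RNA was taken after 6 h or 24 h. Each of the 4 combinations was measured on 1 array, an Affymetrix GeneChip Human Exon 1.0 ST, after labelling of 100 ng of total RNA. No separate cultures of the same treatment and time were analysed here.

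The authors' deposited value table holds log2 expression values for 27631 gene-level probe sets on the 4 arrays. The log2 scale was read from the values, which ran from 2.48 to 13.6. The array medians were 4.39 and 4.40 for DMSO at 6 h and 24 h, and 4.40 and 4.41 for C646 at 6 h and 24 h. The quartiles also lay close together, so the arrays had been brought to a common scale before deposit. The summarisation and normalisation method is not given in the sources used here. The genome build hg19 comes from the submitters' processing notes. No sequence or annotation of that build was used, and no coordinates are given. For arrays, the number of arrays limits the precision, and no detection call per probe set was used.

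Gene names came from the platform annotation of the value table. It listed exactly 1 gene symbol for 20429 probe sets, several for 4232 and none for 2970. Symbols were brought up to date through Entrez identifiers with a gene table of the assembly GRCh38.p14, which matched 20362 of the 1-symbol probe sets and left 67 with their original symbol. Probe sets with several symbols were counted but not named, which holds for the one that covers EP300. Probe sets whose mean over the 4 arrays reached the 40th percentile of all probe sets, 3.96 on the log2 scale, were kept, leaving 16579 probe sets and 10707 named genes. The other 11052 were set aside as close to background. Where several probe sets carried the same symbol, the one with the highest mean stood for the gene.

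With 1 array per group, the difference between C646 and DMSO at each time is a log2 difference of an array against an array. It has no replicate check and no p-value. Probe sets were counted when they differed at least 2-fold. The same was done for 24 h against 6 h within each treatment and for the difference between both C646 effects. The model of treatment over both times was limma on all 4 arrays with time and treatment as terms, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, which left 1 residual degree of freedom. Its error is the disagreement between both times' effects, not the spread of replicate cultures. With 1 array left out, the time term was dropped too, which again left 1. Leaving out the C646 array of 6 h sets the C646 array of 24 h against both DMSO arrays, and the lone C646 array is then assumed to vary as the vehicle arrays did. The relation of the 6 h and 24 h effects is given as Pearson's r and Spearman's rho across probe sets, which are not independent replicates. Both effects share no array.

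There were 32 gene lists, covering the cell cycle, p53 targets, DNA repair, melanocyte and invasive programmes, signalling outputs, stress responses, metabolism, chromatin enzymes, reference genes and markers of 4 other cell types. For each list the median log2 difference was set among 10000 random lists of the same size, matched on mean expression. A list was called when its median lay in the outermost 2.5% on either side. By chance 1.6 of the 32 lists would be called at each time if their members varied independently. Members that vary together can raise that number, and 11 of the 32 were called between the DMSO arrays. The percentile describes these arrays and is not a test between conditions. Some lists share members: p53 targets and apoptosis regulators share 3, MAPK output and immediate early genes share 4.

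The genes named in the text followed a fixed rule. At each time the 12 highest and 12 lowest single-symbol genes were taken by C646 minus DMSO difference. For the model over both times the 8 highest and 8 lowest effects were taken, by size where no gene passed. For the time comparisons and the difference of effects, 6 at each end were taken. Each list contributed its 2 highest and 2 lowest members by mean effect and every member that differed at least 2-fold. CREBBP was always included, as EP300 would have been with a probe set of its own, small RNA genes and symbols starting with LOC were left out, and 274 genes resulted. The groups, lists, filter, tests, naming rule and most alternatives were set before the data were examined. Genes named outside the rule are said to be so where they appear.

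The calculations were tested on simulated data. In the model over both times, with the error that the real fit had, 3% of probe sets planted at 2-fold and 91% of those planted at 4-fold were recovered, with 8 false calls among 16579 probe sets. With the smaller error of the vehicle arrays, 100% were recovered at either size, with 7 false calls. For the 24 h C646 array against both DMSO arrays, 0% were recovered with the first error and 100% with the second, with 13 false calls in the latter. In the list test at 24 h, 4 of 100 unchanged random lists were called, and 100 of 100 lists shifted by 0.25 were called. Those lists were drawn at random, so these rates need not hold for lists whose members vary together.

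The alternatives were centring of each array, quantile normalization, no filter, a filter at the 60th percentile, a floor at the 25th percentile, a 1.5-fold threshold, 1 probe set per gene, the mean of all probe sets of a gene, random lists without matching, and other settings of limma. After the data had been seen, 2 alternatives were added: each C646 array against the mean of both DMSO arrays, and lists restricted to probe sets numbered among those of their own gene's chromosome. In the former, the control includes the DMSO array of the other time, so drift of the vehicle between the times enters. The latter followed from the finding that 9.39% of the placed probe sets carry numbers that fall among those of another chromosome, as a related copy of the gene would. This was so for 23 of the 274 named genes, and 39 had a further probe set above the filter. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.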

Results

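The study asked how transcription in melanoma cells responds when the acetyltransferase activity of p300 is blocked. WM35 is a cell line from a melanoma in its radial growth phase. C646 is a small-molecule inhibitor of the histone acetyltransferases p300 and CBP. Cells were exposed to C646 or to its solvent DMSO for 6 h or 24 h, and each of the 4 conditions was measured on 1 exon array. Differences between arrays are log2 differences, C646 minus DMSO, and none has a replicate check. Across all 27631 probe sets, the DMSO arrays of 6 h and 24 h and the C646 array of 6 h correlated with each other at 0.991 to 0.996. The C646 array of 24 h correlated with the other arrays at 0.976 to 0.979.

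The transcript of CREBBP, which encodes CBP, differed by -0.11 between C646 and DMSO at 6 h and by 0.016 at 24 h. Histone acetyltransferases and bromodomain proteins as a list had medians of -0.042 at 6 h and -0.10 at 24 h over 20 measured members, inside the central range of random lists at both times. At 24 h this list was called lower with the mean of all probe sets of a gene (-0.11) and with probe sets numbered among those of their own gene's chromosome (-0.10), a restriction chosen after seeing the data. The list held members that went apart at 24 h. CITED2, which binds p300 and CBP, was higher by 1.56, ATAD2 was at -2.35, HAT1 at -0.62 and KAT2B at 0.41. Histone deacetylases and sirtuins had medians of 0.010 and 0.094, with SIN3A at -0.44 and HDAC10 at 0.40 after 24 h.

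After 6 h, mitotic genes were lower and melanocyte genes were higher under C646. The G2 and mitosis list had a median of -0.33, below all of its 10000 random lists, and 41 of its 42 measured members lay below 0. Examples were HMGB2 at -0.83, the kinesin KIF11 at -0.67, the kinetochore gene NDC80 at -0.65 and CENPE at -0.61. The melanocyte and pigmentation list had a median of 0.29, above all of its random lists, with 18 of 21 members above 0. IRF4 was at 0.86, S100B at 0.61 and MCOLN3 at 0.47, while TYRP1 was at -0.27. Vehicle cells drifted on the same lists between 6 h and 24 h, by a median of -0.22 for G2 and mitosis and -0.10 for the melanocyte list.

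Few single genes differed by 2-fold at 6 h. Of 16579 probe sets, 21 were at least 2-fold higher and 19 at least 2-fold lower, against 9 and 15 between the DMSO arrays of both times. The highest named genes were the hexokinase gene HK2 at 1.38, PPARGC1A at 1.37, FAHD2A at 1.14, ID3 at 1.14, TCAF2 at 1.11, DCUN1D3 at 1.10, NCAM1-AS1 at 1.05, CD96 at 1.03, LINC00847 at 1.02, B3GALT9 at 1.02, FYB1 at 1.01 and the histone gene H3C2 at 1.00. PPARGC1A, which encodes a coactivator of mitochondrial genes (probe set 2763550), read 4.46 with DMSO and 5.82 with C646. The lowest were CHORDC1P4 at -1.59, the kinase gene YES1 at -1.28, the histone gene H2BC3 at -1.26, MMS22L at -1.13, CDV3 at -1.12, TNFAIP6 at -1.12, SYNC at -1.11, YWHAQP8 at -1.11, ARPC3 at -1.03, INO80D at -1.01, VANGL1 at -0.999 and ACTBL2 at -0.96. The probe sets of HK2, DCUN1D3, YES1, CDV3, SYNC and ARPC3 are numbered among those of another chromosome. A second HK2 probe set was at 0.95, that of YES1 was at -0.090 and the others of CDV3 had a median of -0.20. Among placed probe sets that differed 2-fold at 6 h, 7 of 27 were so numbered (25.9%, Wilson 95% interval 13.2 to 44.7%), against 9.39% of all placed probe sets. Histone genes are near-identical copies, so values of a single one are uncertain.

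Of the 32 lists, 12 were called at 6 h, against 11 between the DMSO arrays of both times. Besides the melanocyte list, 3 lists lay above their random lists. NRF2 response genes had a median of 0.14 with 20 of 22 members above 0, among them ABCC2 at 0.33 and FTL at 0.23. Integrated stress and unfolded protein response genes had a median of 0.10, with DDIT3 at 0.42. MYC targets and ribosome biogenesis genes had a median of 0.081, with MYC at 0.37, a call that quantile normalization ended (0.077). Of the lists below, inflammatory and secreted factors had a median of -0.14 with 21 of 31 members below 0, including PTGS2 at -0.43 and CCL20 at -0.33, while STC1 was at 0.54. Immediate early genes had a median of -0.13 with 16 of 23 members below 0, including JUNB at -0.63 and IER2 at -0.57. The medians were -0.14 for replication-dependent histones, -0.11 for DNA damage response, -0.11 for the invasive and mesenchymal-like state, -0.096 for chromatin modifiers and -0.084 for DNA replication. Against the mean of both DMSO arrays, an alternative chosen after seeing the data, histones (-0.057), DNA damage response (-0.047), the invasive state (-0.059) and DNA replication (-0.036) were no longer called. Quantile normalization ended the call of histones (-0.068), and that of inflammatory factors ended without the filter (-0.054).

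**Figure D1:**
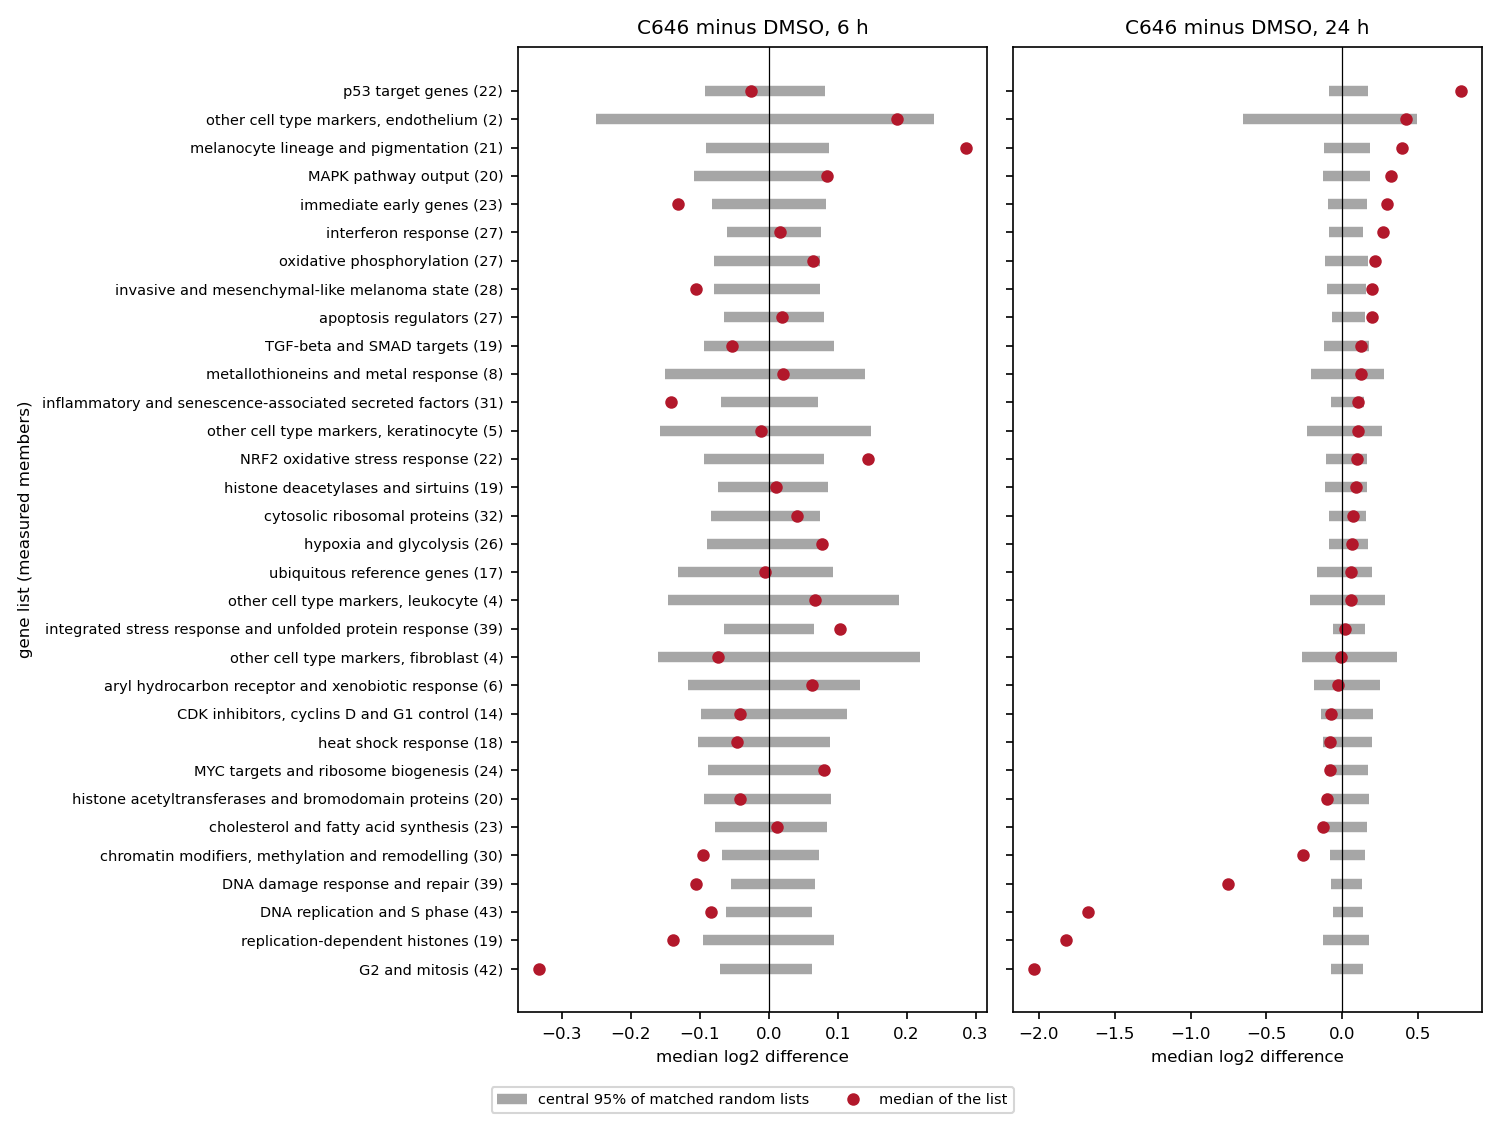
Median log2 difference, C646 minus DMSO, of each of the 32 gene lists at 6 h (left) and 24 h (right), with the number of measured members in brackets. Points are list medians and grey bars the central 95% of 10000 random lists matched on expression. G2 and mitosis sits at -0.33 and -2.03, p53 target genes at -0.026 and 0.78.

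After 24 h, C646-treated cells had lower levels of genes of the dividing cell. The G2 and mitosis list had a median of -2.03, with 38 of 42 members at least 2-fold lower. DNA replication and S phase had a median of -1.68, with 37 of 43 members at least 2-fold lower, and replication-dependent histones had a median of -1.82, with 12 of 19. All 3 medians lay below every random list, and no member of these lists was 2-fold higher. Target genes of the tumour suppressor p53 went the other way, with a median of 0.78, above every random list, and 7 of 22 members at least 2-fold higher.

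Among mitotic genes, the proliferation marker MKI67 was at -2.81, cyclin A2 (CCNA2) at -2.86, topoisomerase TOP2A at -2.73, the spindle gene ASPM at -2.90 and the cyclin-dependent kinase gene CDK1 at -2.13. CDC25B at -0.75 and PTTG1 at -0.62 were among the 4 that did not reach 2-fold. Among replication genes, cyclin E2 (CCNE2, probe set 3145107) was at -3.67, the transcription factor E2F8 at -3.28, CLSPN at -2.84, the helicase loader CDC6 at -2.72 and MCM4 at -2.68. PCNA at -0.47 and ORC6 at 0.15 were among the 6 that did not reach 2-fold, and both probe sets are numbered among those of another chromosome. Among histones, H2BC3 was at -4.86, H2BC14 at -3.52 and the linker histone H1-5 at -3.29, whereas H4C8 was at -0.0031 and H2BC5 at 0.0043. These lists had drifted in the same direction in DMSO between 6 h and 24 h, by medians of -0.22 for mitosis, -0.14 for replication and -0.16 for histones.

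DNA damage response and repair genes had a median of -0.75 at 24 h, with 13 of 39 members at least 2-fold lower. RAD51AP1 was at -2.87, XRCC2 at -2.42, the helicase BLM at -2.40 and BRCA1 at -1.25, while ATR was at 0.16 and LIG4 at 0.32. Chromatin modifiers had a median of -0.26, with 5 of 30 at least 2-fold lower: UHRF1 at -3.86, HELLS at -2.30, the methyltransferase EZH2 at -1.42, ASF1B at -1.42 and SUV39H1 at -1.29. UHRF1 is also on the replication list. Cholesterol and fatty acid synthesis genes had a median of -0.13, with 17 of 23 below 0 and FDPS at -0.28.

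The p53 targets at least 2-fold higher at 24 h were EDA2R at 1.55, the p53 ubiquitin ligase gene MDM2 (probe set 3421300) at 1.48, PHLDA3 at 1.45, TP53I3 at 1.32, the death receptor gene FAS at 1.23, TP53INP1 at 1.11 and BAX at 1.00. CDKN1A, which encodes the cell cycle inhibitor p21, was at 0.85. At 6 h the same list had a median of -0.026, inside its random range, with FAS at -0.46, but against the mean of both DMSO arrays it was called lower (-0.12). In DMSO it drifted between the times by a median of 0.097, which enters that mean. Apoptosis regulators had a median of 0.19, with CASP9 at 0.64 and APAF1 at -0.67, and the p53 targets FAS, BAX and TNFRSF10B belong to this list as well.

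**Figure D2:**
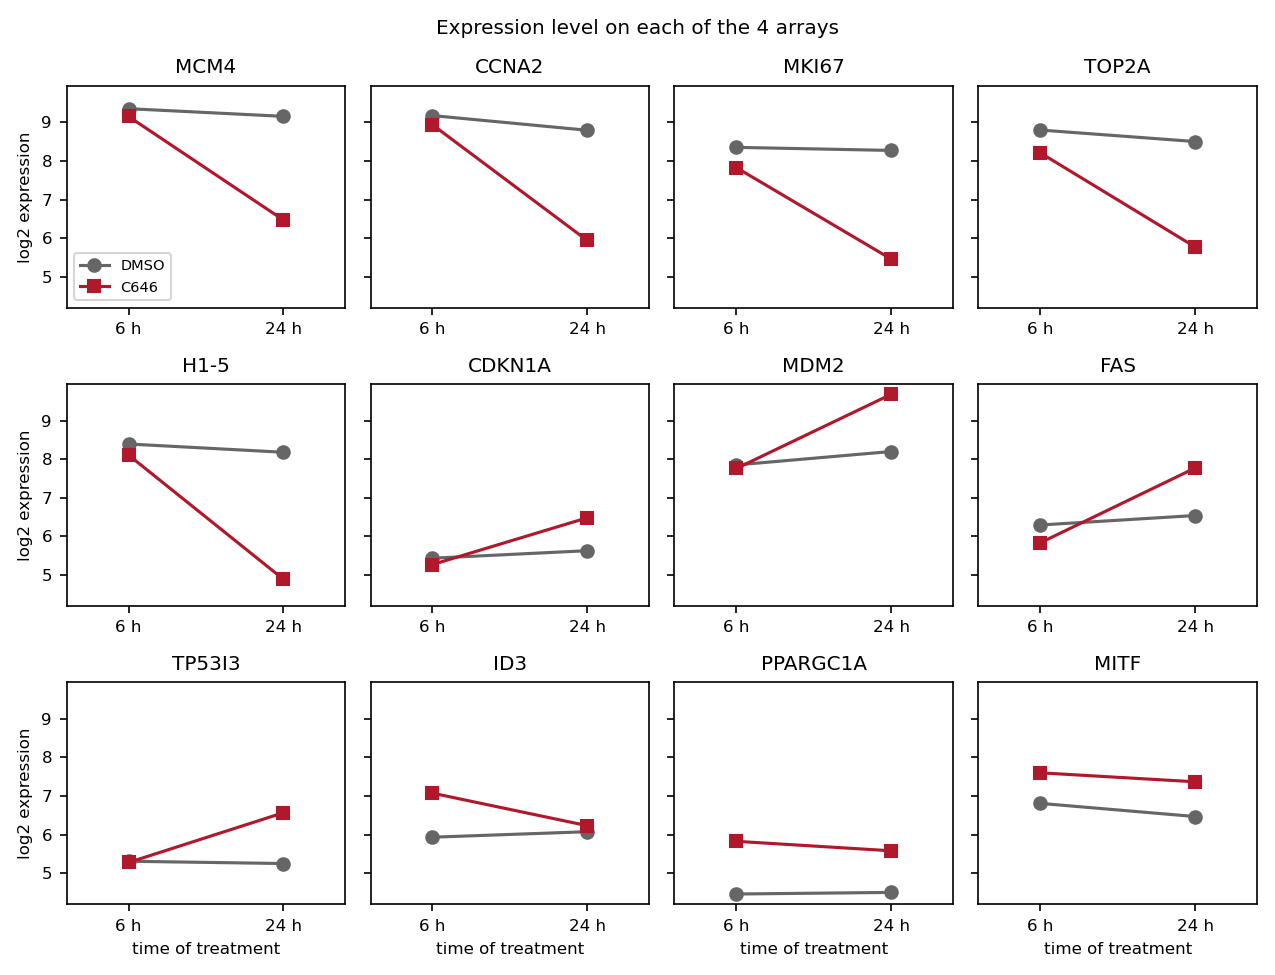
Log2 expression of 12 genes on each of the 4 arrays, against time of treatment, with DMSO in grey circles and C646 in red squares. At 24 h, C646 minus DMSO is -2.81 for MKI67, -2.86 for CCNA2, 1.48 for MDM2 and 1.23 for FAS, while PPARGC1A is higher with C646 at both times.

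The melanocyte list had a median of 0.40 at 24 h, above every random list, with S100B at 1.49, MCOLN3 at 1.02, IRF4 at 0.88 and CDH1 at -0.42. MITF, the master transcription factor of the lineage, was at 0.79 and 0.90 at 6 h and 24 h, and was chosen after its values were seen. MAPK pathway output had a median of 0.32, with ETV4 at 0.76, ETV1 at 0.72 and DUSP5 at -0.79. At 6 h this list was inside its random range at 0.084 (percentile 97.4), but it was called higher with the mean of all probe sets of a gene (0.084) and against the mean of both DMSO arrays (0.14). Immediate early genes had a median of 0.29, with FOS at 0.96 and EGR3 at 1.51. Interferon response genes had a median of 0.27, with OAS2 at 1.03, OAS1 at 0.59 and OAS3 at -0.58, after 0.017 at 6 h. The median was 0.16 without the filter and 0.41 with the filter at the 60th percentile, and the list was called with both. Oxidative phosphorylation genes had a median of 0.22 with 24 of 27 above 0, among them PPARGC1A at 1.08 and COX5B at 0.73. At 6 h this list was inside its range at 0.065, but it was called higher with the mean of all probe sets of a gene (0.072) and with the chromosome restriction (0.10). The invasive and mesenchymal-like list had a median of 0.20, with NGFR at 0.62, SNAI2 at 0.58 and ZEB1 at -0.47, and its call ended without the filter (0.059).

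Of the 32 lists, 14 were called at 24 h, against 11 between the DMSO arrays of both times. The remaining lists lay inside their random ranges at 24 h. Inflammatory and secreted factors had a median of 0.10, NRF2 response genes 0.10, the integrated stress response 0.016 and MYC targets -0.084. Within the stress list DDIT3 was at 1.17, whereas MTHFD2 was at -0.94 and CHAC1 at -0.88. The lists inside their ranges at both times, with medians at 6 h and 24 h, were G1 regulators (-0.042 and -0.077), heat shock (-0.046 and -0.080), metallothioneins (0.021 and 0.13), the aryl hydrocarbon response (0.063 and -0.027), hypoxia and glycolysis (0.077 and 0.062), ribosomal proteins (0.041 and 0.072) and TGF-beta targets (-0.054 and 0.13). Reference genes had medians of -0.0051 and 0.058. Apoptosis regulators at 6 h were at 0.019 and cholesterol synthesis genes at 0.011. Markers of other cell types were measured in few members: keratinocyte genes had medians of -0.010 and 0.10, fibroblast genes -0.073 and -0.0065, leukocyte genes 0.068 and 0.055, and the 2 endothelial genes 0.19 and 0.42. Other settings called some of these lists. Against the mean of both DMSO arrays, heat shock was lower (-0.16) and endothelium higher (0.33) at 6 h, and MYC targets were lower at 24 h (-0.13). Hypoxia and glycolysis was called higher at 6 h with quantile normalization (0.10), with random lists without matching (0.077) and with the chromosome restriction (0.11), which also called ribosomal proteins (0.10). Endothelium was called at 6 h with the filter at the 60th percentile (0.53) and at 24 h with the mean of all probe sets (0.42).

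Of 16579 probe sets, 189 were at least 2-fold higher and 414 at least 2-fold lower at 24 h. The lowest named genes were FAM111B at -5.41, which read 9.21 with DMSO and 3.80 with C646, H2BC3, the histone gene H3C12 at -4.13, UHRF1, CCNE2, DEPDC1 at -3.63, H2BC14, the replication factor gene TICRR at -3.48, CDCA8 at -3.29, H1-5, E2F8 and the phosphatase gene CDC25A at -3.22. UHRF1 and DEPDC1 probe sets are numbered among those of another chromosome, and their other probe sets were at -2.95 and -1.94. The highest were ZNRD2-DT at 2.55, PRSS35 at 2.51, the long noncoding RNA PURPL at 2.40, the sulfatase gene SULF2 at 2.16, DNAI3 at 2.12, the ubiquitin ligase gene FBXO32 at 1.97, TRIM22 at 1.94, SETDB2 at 1.77, the Wnt antagonist gene DKK1 at 1.72, YPEL2 at 1.71, IL16 at 1.71 and CEMIP at 1.65.

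The C646 array of 24 h was also set against both DMSO arrays in limma. There, 1108 probe sets rose and 1144 fell at an adjusted p under 0.05. All 42 measured mitotic genes fell, as did 42 of 43 replication genes, 25 of 39 repair genes and 13 of 19 histones. Of 22 p53 targets 18 rose, and 20 rose when adjusted over the list alone. In the melanocyte list 6 rose and 1 fell, in the interferon list 7 rose and 1 fell, and the corresponding counts adjusted over the list alone were 10 and 1 for each. MDM2 (limma adjusted p = 0.012), CDKN1A (0.018), CCNE2 (0.0029) and MKI67 were among these. SETDB2 (0.077), ZNRD2-DT (0.12) and EGR3 (0.19) were not; DMSO at 24 h differed from DMSO at 6 h by -0.83, -1.42 and -1.02 for these genes. This comparison takes the spread from the DMSO pair alone, and in simulated data with the larger error of the model over both times it recovered 0% of 4-fold changes. Without a time term it also takes in drift of the vehicle, which ran the same way for the mitosis, replication, repair, histone and p53 lists.

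An effect shared by both times was sought with limma on all 4 arrays. The estimate is the mean of both times' effects, so a large one can come mostly from 1 time. CCNE2, for example, was at -0.23 at 6 h and -3.67 at 24 h. No probe set passed, with 0 called and a lowest limma adjusted p of 0.448. At an unadjusted limma p under 0.05 there were 1828 probe sets, where 829 would be met by chance if they varied independently. Probe sets that vary together can move that count either way. The largest estimates among named genes were H2BC3 at -3.06 ± 0.91 (SE), FAM111B at -2.69 ± 1.36, H3C12 at -2.41 ± 0.86, DEPDC1 at -2.23 ± 0.71, UHRF1 at -2.10 ± 0.88, CCNE2 at -1.95 ± 0.86, KIF14 at -1.94 ± 0.62 and TICRR at -1.93 ± 0.78. On the other side were PRSS35 at 1.39 ± 0.57, PURPL at 1.36 ± 0.52, ZNRD2-DT at 1.36 ± 0.60, CEMIP at 1.30 ± 0.21, IL16 at 1.24 ± 0.26, PPARGC1A at 1.22 ± 0.12, DNAI3 at 1.19 ± 0.47 and YPEL2 at 1.16 ± 0.30. Adjusted over the list alone, 6 genes passed, all higher: IRF4 (limma adjusted p = 0.018), MITF (0.018) and RAB38 (0.037) of the melanocyte list, PPARGC1A (0.013) of oxidative phosphorylation, CYP1A1 (0.0068) of the aryl hydrocarbon list and KDR (0.014) of the endothelial markers. RAB38 was chosen after its values were seen. This adjustment was made within each list and not across the lists, so genes can pass in some lists by chance. The aryl hydrocarbon list had 6 measured members and the endothelial list 2, so few tests were adjusted for there. None of these genes passed when adjusted over all probe sets. Without the C646 array of 24 h the model called 0, with 2619 at an unadjusted p under 0.05. It called 0 without either DMSO array, with 498 and 292 at that p.

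The effects at 6 h and 24 h ran in the same direction for most of the genes that differed. Of 603 probe sets at least 2-fold different at 24 h, 509 (84.4%) had the same sign at 6 h, and of 40 at 6 h, 31 had the same sign at 24 h. Across probe sets the effects correlated at r = 0.404 and rho = 0.413, and 12 probe sets differed at least 2-fold at both times, all in the same direction. They included PPARGC1A, FYB1, B3GALT9, LINC00847, H2BC3, MMS22L, CHORDC1P4, CDV3, TNFAIP6 and YWHAQP8. ID3 was an example of a difference at 6 h that was small at 24 h (0.16).

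**Figure D3:**
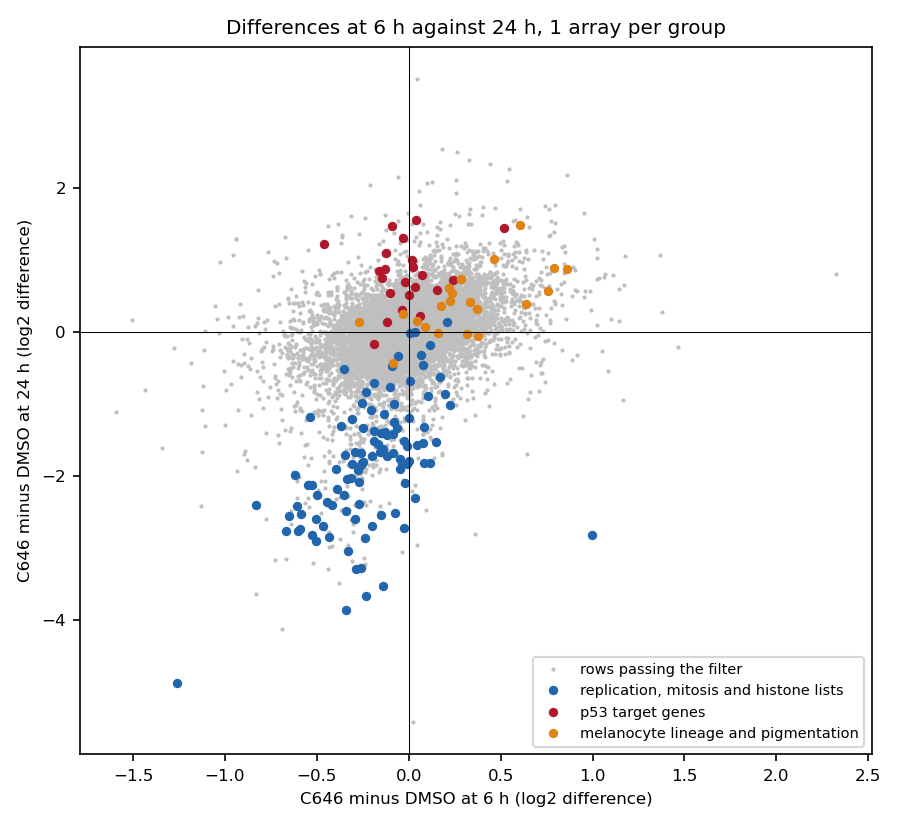
Log2 difference, C646 minus DMSO, at 6 h (horizontal axis) against 24 h (vertical axis) for the 16579 probe sets above the filter, 1 array per group. Blue points are genes of the replication, mitosis and histone lists, red points p53 targets and orange points melanocyte genes. Most blue points lie below 0 on both axes, all red points but 1 lie above 0 on the vertical axis, and r across all probe sets is 0.404.

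The effect of C646 was larger at 24 h than at 6 h for the cell cycle lists. The difference between both effects had a median of -1.62 for mitosis, -1.59 for replication, -1.40 for histones and 0.81 for p53 targets, each outside all random lists, and 156 probe sets were at least 2-fold higher and 364 at least 2-fold lower. Among named genes, FAM111B at -5.44, H3C2 at -3.82, H2BC3 at -3.60, UHRF1 at -3.52, H3C12 at -3.43 and CCNE2 at -3.43 had the lowest values. ZNRD2-DT at 2.37, PRSS35 at 2.25, REP15 at 2.24, SULF2 at 2.22, PURPL at 2.07 and ACTBL2 at 2.03 had the highest. Of the 32 lists, 17 had a difference in the outermost 2.5% of their random lists. Immediate early genes were at 0.44 with 23 of 23 members above 0, MAPK output at 0.26, the invasive and mesenchymal-like state at 0.24, inflammatory factors at 0.21, interferon response genes at 0.20, TGF-beta targets at 0.18 and apoptosis regulators at 0.14. DNA damage response genes were at -0.63, G1 regulators at -0.19, chromatin modifiers at -0.17, MYC targets at -0.17, cholesterol synthesis genes at -0.15 and integrated stress genes at -0.080. The melanocyte list did not differ between the times beyond its random lists, at 0.11. There is no p-value for these differences, since they leave no residual degree of freedom.

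In DMSO alone, 9 probe sets were at least 2-fold higher and 15 at least 2-fold lower at 24 h than at 6 h. The highest named genes were FYN at 1.91, the p53-responsive gene PTCHD4 at 1.68, PCLO at 1.26, MYLK at 1.13, DDHD1 at 1.02 and HSPA4L at 0.95. The lowest were MAP3K9 at -1.57, ZNRD2-DT at -1.42, the splicing factor gene TRA2B at -1.30, ANKRD36B at -1.02, PRICKLE1 at -1.02 and EGR3 at -1.02. The FYN probe set is numbered among those of another chromosome, and its other probe set was at -0.023. Of the 32 lists, 11 lay in the outermost 2.5% of their random lists on either side. Heat shock genes drifted by a median of 0.085, NRF2 genes by 0.050 and chromatin modifiers by 0.030. DNA damage response genes drifted by -0.10, close to their C646 difference of -0.11 at 6 h, integrated stress genes by -0.083 and the 2 endothelial genes by -0.29. The drifts of the mitosis, replication, histone, p53 and melanocyte lists, given above, were the others.

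In C646, 144 probe sets were at least 2-fold higher and 399 at least 2-fold lower at 24 h than at 6 h. The highest named genes were PCLO at 2.54, PTCHD4 at 2.45, TRIM22 at 2.34, SULF2 at 2.31, PURPL at 2.23 and EDA2R at 1.96. The lowest were FAM111B at -5.67, H3C12 at -3.84, H2BC3 at -3.68, H2BC14 at -3.58, CCNE2 at -3.57 and UHRF1 at -3.39. The time differences in DMSO and C646, which share no array, correlated across probe sets at 0.290.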

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

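The tests of signal scaling, of a one-off event and of a general stress response were chosen only after the result was seen.

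Some results lay on opposite sides of 0 at 6 h and 24 h, a difference that was not tested against replicates. The invasive and mesenchymal-like list had a median of -0.11 at 6 h and 0.20 at 24 h, and the immediate early list one of -0.13 and 0.29. The difference between both effects was at percentile 99.97 of matched random lists for the former and 100 for the latter. ACTBL2 was at -0.96 and 1.07, REP15 at -0.94 and 1.30, and the histone gene H3C2 at 1.00 and -2.82. Among probe sets below the filter, which the report's counts and lists leave out, 2 differed at least 2-fold at 6 h and 12 at 24 h, against 1 between the DMSO arrays.

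Lower replication, mitosis and histone genes at 24 h rest on a single C646 array. A stretch or compression of that array's signal would move genes of like intensity alike. These genes instead lay at -1.84 relative to the median of matched random lists. An exchange of time labels between the C646 arrays was expected to make the time differences in DMSO and C646 oppose each other. Outside the cell cycle and p53 lists those differences correlated at 0.283. Genes outside these lists that fell with them, such as CDC25A (-0.258 in DMSO, -3.24 in C646), can raise r whichever array is which. An exchange is therefore not excluded. In the separate 6 h pair the G2 and mitosis list was at percentile 0 of its matched lists, also against the mean of both DMSO arrays (-0.23), but replication and histones, at -0.084 and -0.14 in that pair, were at percentiles 7.3 and 7.43 against that mean, and histones at 6.74 under quantile normalization. The DMSO arrays alone put mitosis (-0.22) and replication (-0.14) at percentile 0, so such a percentile in a single pair arises without C646. A one-off event in the 24 h culture or array therefore stays open for the direction and for the size at 24 h, a median of -1.81, and cannot be told apart from an effect of C646 without a further 24 h culture.

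Higher p53 targets at 24 h were weighed in the same way. After subtraction of the median of matched random lists they remained at 0.738, which argues against a stretch or compression of the array's signal. A general response of stress genes would raise the integrated stress, heat shock or NRF2 list by a like amount. The highest of their medians, already seen when this test was chosen, was 0.0997. That bears only on stress that raises these lists, and other forms of stress stay open. An effect of C646 on p53 targets stays open as a hypothesis, found and tested on the same arrays. So does an event of that single culture, since the list was at -0.026 at 6 h, inside its random range. Its lower call at 6 h against the mean of both DMSO arrays (-0.12) takes in the rise of 0.097 in DMSO between the times.

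The effects at 6 h and 24 h ran together across probe sets, although they share no array. The correlation was 0.404 with and without the cell cycle and p53 lists. Leaving them out kept 16453 of 16579 probe sets, among them that of CDC25A. It therefore does not show that r is independent of cell cycle genes. A difference in how the C646 and DMSO arrays were handled could give such a correlation. It was expected to act on dim probe sets as much as on bright ones, and below the filter r was 0.161, under the bound set beforehand for excluding it. That bound does not decide the question, because r also falls where noise makes up more of the values, which may hold near background. The SD between the DMSO arrays of both times, 0.133 there against 0.173 above the filter, does not measure that share. Handling and treatment cannot be told apart here, as each C646 array may have been processed with the other.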

How the results depend on the processing

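Settings chosen only after the result was seen were the mean of both DMSO arrays and the restriction to probe sets numbered on their gene's chromosome. No result reversed its direction. Counts stayed within 1.5 times in 56 of 74 comparisons with an alternative, list calls in 552 of 576, and the relation of both effects in 15 of 15. Of 2192 values of named genes, 2100 moved by less than the vehicle spread and 92 by more. Signal close to background limits the 11052 dim probe sets, and 1 array per group limits all counts.

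With a 1.5-fold threshold the counts higher and lower were 166 and 209 at 6 h, 822 and 886 at 24 h, 98 and 101 for time in DMSO, 650 and 861 for time in C646, and 707 and 812 for the difference of effects, by construction of a lower threshold. With 1 probe set per gene, fewer probe sets were counted: 12 and 10 at 6 h, 104 higher at 24 h, 5 and 7 for time in DMSO, 76 higher for time in C646 and 69 higher for the difference. A filter at the 60th percentile left 12 higher at 6 h. Leaving out 1 array at a time, limma called 0 to 1108 probe sets higher and 0 to 1144 lower. The calls came without the C646 array of 6 h, and the other arrays left out in turn gave 0, with 292 to 2619 at an unadjusted p under 0.05.

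For lists, the cause of a changed call was not tested. The mean of both DMSO arrays includes the vehicle of the other time, so drift in DMSO enters that setting by construction. Against the mean of both DMSO arrays at 6 h, calls ended for replication (-0.036), DNA damage (-0.047), the invasive state (-0.059) and histones (-0.057). Calls appeared there for p53 targets (-0.12), MAPK output (0.14), heat shock (-0.16) and endothelium (0.33), and for MYC targets at 24 h (-0.13). Without the filter the calls of the invasive state at 24 h (0.059) and of inflammatory factors at 6 h (-0.054) ended. Quantile normalization at 6 h ended those of histones (-0.068) and MYC targets (0.077) and added hypoxia (0.10). The mean of all probe sets added MAPK output (0.084) and oxidative phosphorylation (0.072) at 6 h, and acetyltransferases (-0.11) and endothelium (0.42) at 24 h. Restriction to the gene's chromosome added acetyltransferases at 24 h (-0.10) and hypoxia (0.11), ribosomal proteins (0.10) and oxidative phosphorylation (0.10) at 6 h. Random lists without matching added hypoxia at 6 h (0.077), and the filter at the 60th percentile added endothelium (0.53).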

Other observations

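The test of noncoding probe sets was chosen only after the result was seen, and so was the choice of MITF and of the further genes named here.

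PPARGC1A and MITF were higher with C646 at both times, PPARGC1A by 1.37 at 6 h and 1.08 at 24 h and MITF by 0.79 and 0.90. A hypothesis is that the transcripts of MITF target genes were higher as a group. It was tested on 51 genes known as MITF targets outside the melanocyte list, of which 40 were measured. Their median was 0.156 at 6 h and 0.154 at 24 h, with 29 of 40 above 0 at each time, and the lower of both percentiles among matched random lists was 99.05. CEACAM1 was at 1.18 at 24 h, MBP at 0.74 and 0.62 and TBC1D16 at 0.62 and 0.15, whereas DIAPH1 was at -0.87 at 24 h. The shift is small for single genes, and it is consistent with higher MITF activity without excluding other regulators of the same genes.

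Several of the highest single genes were long noncoding RNAs. Among them were PURPL at 2.40 and ZNRD2-DT at 2.55 at 24 h, and LINC00847 at 1.02 at 6 h. ZNRD2-DT also fell in DMSO between 6 h and 24 h, which enters its difference at 24 h. As a class, 225 probe sets named as antisense, divergent or intergenic noncoding RNAs had medians of 0.0739 at 6 h and 0.151 at 24 h. The lower of both percentiles among matched random lists was 100, and 143 and 159 of these probe sets lay above 0. Their percentile between the DMSO arrays was not taken. Noncoding transcripts may thus be shifted upward as a class by a small amount, and the arrays give no way to separate this from a change at probe sets of low signal that matching on mean expression does not cover.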
